A study of Mus musculus with 6 samples.

How the data were processed

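The series holds 6 Smart-seq2 libraries of FACS-sorted mouse round spermatids at postnatal day 28, 3 labelled Eif5a SKO and 3 wild type. The deposited table gives whole-number read counts per gene symbol, not normalized, for all 6 libraries in 1 file. Its columns name the knockout libraries cKO and the others WT, each with a number, and cKO was taken as Eif5a SKO and the numbers as the labels' replicate numbers. Library preparation used polyadenylated RNA and paired reads of 150 bases, per the labels' protocols. Per the submitters' processing notes, FastQC, Trim Galore 0.6.4, HISAT2 2.0.5 and featureCounts 1.5.0-p3 of Subread were used, with the builds GRCm38 and mm10, which are names of the same assembly. The annotation release, the strand setting, the treatment of reads that map to several places and any filter on genes are not given in the sources used here. Reads of overlapping genes on opposite strands therefore cannot be told apart, and reads of near-identical copies may be lost or split. Amplified cDNA without molecular identifiers gives counts of reads, not of molecules.

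Gene positions, biotypes, exonic lengths and GC content came from GENCODE release M21 on GRCm38. Of the 22770 symbols, 22062 matched by symbol and 210 by a synonym, and 498 did not match. Of the 19776 genes tested, 349 had no match and entered no analysis by chromosome, length or GC. For each gene, the share of 31-base words of its longest transcript that occur in another gene was counted as a measure of shared reads. The overlap of each named gene's exons with exons of other genes was also counted. The table holds 0 mitochondrially encoded genes.

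Counts were analysed in R 4.3.3. Genes were kept by the filterByExpr rule of edgeR 4.0.16 with the group (minimum count 10), libraries were scaled by TMM factors, and the groups were compared with edgeR's quasi-likelihood test (robust dispersion and robust fit) with Benjamini-Hochberg adjustment and an adjusted p under 0.05. The filter removed 2994 genes that together held 0.0182% to 0.0326% of a library's counts. Fold changes are SKO over wild type on the log2 scale, and standard errors are those implied by the F statistic. The TMM factors were 0.909, 0.884 and 0.97 for SKO replicates 1, 2 and 3 and 1.08, 1.1 and 1.08 for wild type replicates 1, 2 and 3. CPM values use these factors.

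Gene lists were fixed before the data were examined, 28 of them by function or cell type, with X-linked and Y-linked genes as 2 more. The list of mitochondrially encoded transcripts had no member in the table, so 29 were tested. Each list was tested with camera of limma 3.58.1 with a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists. Of the 29 lists 11 were called, all higher in SKO. With the correlation estimated per list 1 was called, the X-linked genes. The fry test, which asks whether a list's genes move on balance in a single direction without comparing them with other genes, called 16 lists, 15 higher and 1 lower. Genes called within a list were counted after adjustment over all genes tested and again after adjustment over the list alone. Of the genes tested, 14 of 20 early round spermatid genes and 15 of 25 elongating spermatid genes also stand in another list. Lists of genes with few reads lost many members, which were absent from the table or removed by the filter. Tested were 12 of 21 Sertoli, 10 of 20 spermatogonial, 11 of 20 Leydig and peritubular and 14 of 23 blood, endothelial and macrophage markers. Of the interferon response genes 12 of 28 were tested. Counts and medians hold for the tested members only. Of the 12 Sertoli markers tested, 2 had a mean of at least 1 CPM in wild type and 1 stands in another list. That mean was reached by 12 of 21 p53 and cell death genes, 5 of 12 interferon response genes, 6 of 11 Leydig and peritubular markers and 6 of 14 blood, endothelial and macrophage markers. Of the 33 sex-linked genes tested, 21 are X-linked, 10 Y-linked and 2 autosomal.

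Named genes follow a rule set before the data were examined. It takes Eif5a, the 8 largest rises and 8 largest falls among genes past the threshold with a mean of at least 5 CPM, groups that do not overlap and a plain gene symbol, and the 4 most abundant such genes in each direction. From each list it takes up to 4 members with the lowest p and a mean of at least 1 CPM. Other list members named, and Gm2098, Cdk16 and the Y-linked genes with few shared words, were chosen after their values were seen. Some genes that the rule takes are not reported here.

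Depth was 52055193 to 60970931 counts per library. On simulated counts with these library sizes, the test called 10.4% of 67 genes changed 1.5-fold, 61.2% of 67 changed 2-fold and 98.5% of 66 changed 4-fold, over 19094 genes tested, and 8.06% of its calls were unchanged genes. Only these genes were changed, far fewer than the 8339 called in the real comparison. The adjustment is milder where many genes change, so the shares called do not carry over to it. With nothing changed in the simulation, where genes vary independently of each other, camera called 0 lists. Each of the 9 other splits of the real libraries into 3 and 3 called 6 to 15. These splits hold both genotypes in each group in unequal numbers and so keep part of the genotype difference. Their calls therefore do not count false calls. No 2 libraries of a group held the same counts (chi-square per gene of 14.8 to 149 against counting error), which does not show whether they came from separate animals, and each was counted as a separate sample. Correlations across genes were 0.976 between SKO replicates 1 and 2, 0.962 and 0.964 between these and SKO replicate 3, and 0.976 to 0.978 among wild type libraries.

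Alternatives chosen before the data were examined were RLE, total-count and upper-quartile scaling, no filter, a filter of at least 5 CPM in 3 libraries, DESeq2 1.42.0, limma-voom with and without quality weights, leaving out each replicate, the replicate number as a block, leaving the 20 genes with the most counts out of the library sizes, and for lists camera with an estimated correlation and fry. After the data were seen, a fit with each library's trend with exonic length and GC removed (natural splines with 5 degrees of freedom) and a fit without X-linked and Y-linked genes were added, and the scalings, the lack of a filter, the other tests and camera with an estimated correlation were also run for the X-linked comparison.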

Results

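Gene expression was measured in mouse round spermatids, the haploid germ cells that have finished meiosis and have not yet begun to elongate. The cells were sorted by FACS from testes at postnatal day 28 and were mainly at step 8, when round spermatids start to reshape. Smart-seq2, which copies polyadenylated RNA into full-length cDNA before library preparation, gave 6 libraries, 3 from wild type mice and 3 from mice labelled Eif5a SKO. Eif5a encodes a translation factor that carries the modified amino acid hypusine, and the labels do not explain the abbreviation SKO. The comparison asks how loss of this factor alters the transcriptome of spermatids at the onset of chromatin remodelling. The table held 22770 genes, with 53299229, 60970931 and 52055193 counts in SKO replicates 1, 2 and 3 and 54156986, 53416955 and 57951763 in wild type replicates 1, 2 and 3. The labels do not say that the 3 libraries of a group came from separate animals, so the p-values may measure only technical spread.

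Eif5a itself was nearly absent from the SKO libraries. The gene lies on chromosome 11 from 69916714 to 69921958 on the minus strand of GRCm38 and is protein-coding. It had 333, 338 and 270 counts in SKO replicates 1, 2 and 3, against 41149, 36162 and 41278 counts in wild type replicates 1, 2 and 3. The mean was 6.17 ± 0.771 CPM (counts scaled to a common library size; SD, n = 3) in SKO and 660 ± 42.3 CPM (SD, n = 3) in wild type, so that 0.935% of the wild type level remained. The log2 fold change was -6.74 with a standard error (SE) of 0.18 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 4.71e-08). The labels do not name the deleted part of the gene, and 14.1% of the 31-base words of its longest transcript also occur in other annotated genes. The paralog Eif5a2 was at 24.1 ± 3.74 CPM in wild type and 27.2 ± 2.81 CPM in SKO (SD, n = 3), a log2 difference of 0.18 that did not pass the same edgeR test (adjusted p = 0.423). Dhps and Dohh, the enzymes that make hypusine, had log2 fold changes of 0.30 and 0.11 (edgeR adjusted p = 0.275 and 0.685).

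In SKO spermatids, transcripts from the X and Y chromosomes were higher as a group, with median log2 fold changes of 1.32 over 735 X-linked genes and 1.5 over 343 Y-linked genes (1.02 and 0.951 with trends in gene length and GC content removed). Of the 343 Y-linked genes, 5 had under 5% of their 31-base words shared with other genes. With an estimated correlation between genes the camera adjusted p was 0.026 for X-linked genes and 0.289 for Y-linked genes, so that the call of the Y-linked genes was lost. Messenger RNAs for cytosolic ribosomal proteins and for the respiratory chain rose in 62 of 79 and 54 of 73 measured members (camera adjusted p = 0.659 and 0.542 with an estimated correlation). Markers of Sertoli cells, the somatic cells that nurse the germ cells, rose from a summed 8.94 ± 5.32 CPM to 149 ± 81.6 CPM (SD, n = 3 each), with a camera adjusted p of 0.324 with an estimated correlation. Apart from Eif5a, the largest falls among genes with a plain symbol, a mean of at least 5 CPM and groups that did not overlap were in the folate enzyme gene Aldh1l1, the testis protease gene Adam21 and the calcium sensor gene Ncs1, at log2 fold changes of -5.13, -4.48 and -4.12.

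Of 19776 genes tested, 4179 were higher and 4160 were lower in SKO at an adjusted p under 0.05 in edgeR's quasi-likelihood test. Changes of 2-fold or more made up 2298 of the rises and 2567 of the falls. The first principal component held 64.6% of the variance and set the 3 SKO libraries (-91.5 to -71.8) apart from the 3 wild type libraries (74.2 to 86.6). SKO replicate 3 lay apart from the other libraries on the second component, which held 13.5% of the variance, at -71.4 against 40.3 and 37.6 for the other SKO libraries. Without SKO replicate 3, 4321 genes were higher and 4823 lower. When libraries were scaled by total counts alone, the median of all genes moved to -0.23 from 0.01, and 2801 genes were higher and 5671 lower. When only genes with at least 5 CPM in 3 libraries were tested, 3056 were higher and 2755 lower, with 1221 rises and 1256 falls of 2-fold or more.

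The largest rises among genes with a mean of at least 5 CPM and a plain gene symbol, which leaves out predicted genes such as the Y-linked Gm28337 (5.52), were in Cst12, Defb19 and Cst9, which Sertoli cells express. Cst12 went from 0.18 ± 0.233 to 14.4 ± 4.01 CPM (SD, n = 3), a log2 fold change of 6.32. Defb19, a beta-defensin gene, had a log2 fold change of 6.23, and Cst9 had 5.30. Next came Pip at 4.44, the lactate dehydrogenase gene Ldhb at 4.28, the lysosomal protease gene Ctsl at 4.11, the glutathione transferase gene Gstm2 at 4.11 and Igfbp6 at 3.75. Their adjusted p in the edgeR test ranged from 4.02e-06 for Pip to 0.00334 for Ctsl, which did not pass with the replicate number as a block (adjusted p = 0.0747). Ldhb and Ctsl share 41.4% and 29.8% of their 31-base words with other genes, so their counts are less certain. The most abundant genes that rose were the testis lactate dehydrogenase gene Ldhc, from 7290 ± 95.7 to 11900 ± 785 CPM (SD, n = 3), Ubb, which encodes polyubiquitin, Gstm5 and Meig1. Their log2 fold changes were 0.70, 0.43, 1.03 and 1.29. Ubb shares 54.1% of its 31-base words with other genes, so its counts are also less certain. The rise of Ubb did not pass the edgeR test with total-count scaling (adjusted p = 0.206) or with the replicate number as a block (adjusted p = 0.076). Nor did it pass without SKO replicate 2 or any single wild type library (adjusted p = 0.0568 to 0.0825). Ldhc was at 0.46 with total-count scaling and Meig1 at 0.75 with length and GC trends removed.

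Aldh1l1 fell from 42.2 ± 2.49 to 1.21 ± 0.232 CPM (SD, n = 3), with a log2 fold change of -5.13 and an SE of 0.20 (edgeR adjusted p = 1.44e-06). It lies on chromosome 6 from 90486427 to 90600203. Adam21 on chromosome 12 fell from 65.9 ± 7.44 to 2.96 ± 0.414 CPM (SD, n = 3), a log2 fold change of -4.48. The falls of Ncs1 (-4.12), the phosphodiesterase gene Pde4b (-4.11), the aminopeptidase gene Rnpep (-4.06) and Dnmt3l (-3.91), whose product assists DNA methyltransferases, were of similar size. Pex6, needed for peroxisome assembly, and Chac1, a glutathione-degrading enzyme, had log2 fold changes of -3.89 and -3.79. The adjusted p of these 8 genes in the edgeR test was between 1.44e-06 and 5.25e-05. The most abundant genes that fell were the alpha-tubulin genes Tuba3a, from 2300 ± 45.2 to 1020 ± 41 CPM, and Tuba3b, from 2270 ± 23.5 to 1010 ± 61 CPM (SD, n = 3). These copies share 51.4% and 43.1% of their 31-base words with other genes, so the counts could not be assigned to either with certainty. Dnaaf1, which helps assemble axonemal dynein, and Rnaseh2a, a subunit of ribonuclease H2, fell, with log2 fold changes of -0.87 and -0.81 (-0.52 and -0.45 with length and GC trends removed).

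Among the 735 X-linked genes tested, 461 were higher and 14 lower in SKO (491 and 14 adjusted over the list alone). The median X-linked log2 fold change was 1.32 (quartiles 0.71 and 1.92), against -0.04 (quartiles -0.68 and 0.54) for 18349 autosomal genes, of which 3450 were higher and 4064 lower. The difference of the medians was 1.36 (camera with a preset correlation, adjusted p = 7.52e-33), and the adjusted p was 0.026 with an estimated correlation. Of 343 Y-linked genes, 225 were higher and 1, the pseudogene Gm2098, was lower (247 and 1 adjusted over the list alone), with a camera adjusted p of 1.21e-24. With an estimated correlation the adjusted p was 0.289. Only 5 of these 343 genes had under 5% of their 31-base words shared. Near-identical copies can share or split the same reads, so the Y-linked counts may not be of independent genes. With length and GC trends removed the medians were 1.02 for X-linked and 0.951 for Y-linked genes (camera adjusted p = 2.02e-22 and 5.21e-11 with a preset correlation). X-linked genes took 2.81 ± 0.12% of all counts in SKO and 1.21 ± 0.05% in wild type, and Y-linked genes 0.638 ± 0.055% and 0.188 ± 0.026% (SD, n = 3). All 3 SKO libraries lay above all 3 wild type libraries in both shares, and an exact two-sided permutation test of 3 against 3 cannot give a p below 0.1. Among X-linked genes with a mean of at least 20 CPM, 183 of 216 were higher and 1, the kinase gene Cdk16, was lower. The autosomal medians lay between -0.16 on chromosome 15 and 0.25 on chromosome 14.

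**Figure D1:**
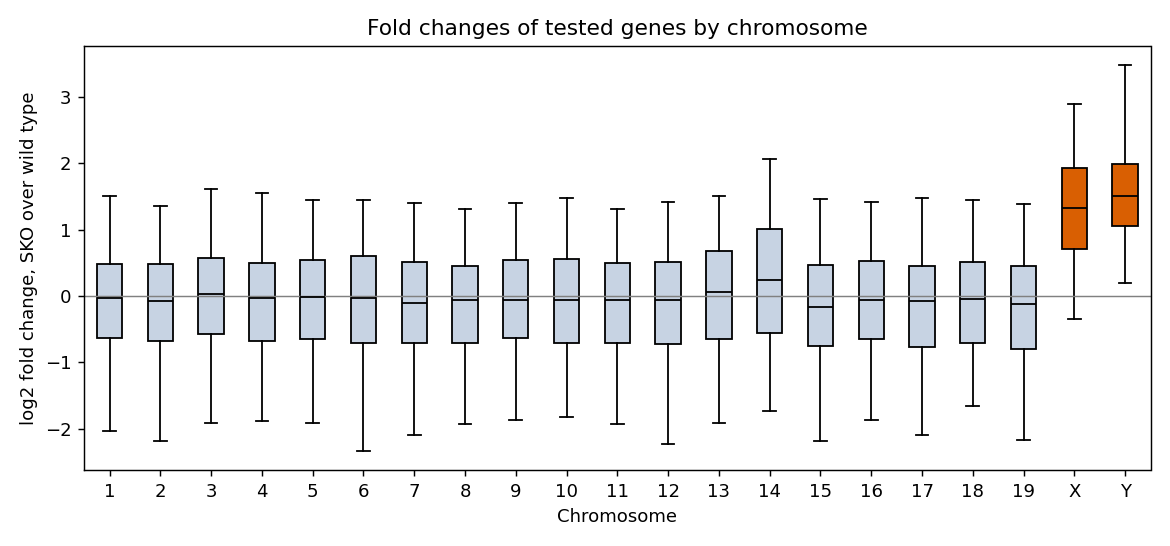
Log2 fold changes (SKO over wild type, vertical axis) of the tested genes on each chromosome (horizontal axis). The line in each box is the median, the box spans the quartiles and the whiskers the 5th to 95th percentiles; the medians were 1.32 for X, 1.5 for Y and between -0.16 and 0.25 for the autosomes.

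The X-linked genes with the lowest p were the multicopy gene Gm1993 (edgeR adjusted p = 2.8e-06), Cypt2 on chromosome X from 105499772 to 105500639, which rose from 70.2 ± 6.44 to 486 ± 51.6 CPM (SD, n = 3), Rhox11 (11.8 ± 0.0881 to 112 ± 20.5 CPM) and Fam122c (97.2 ± 6.06 to 538 ± 43.8 CPM). The log2 fold changes of Cypt2, Rhox11 and Fam122c were 2.79, 3.25 and 2.47 (edgeR adjusted p = 4.02e-06, 4.02e-06 and 4.96e-06). Gm1993 had a log2 fold change of 3.23, which is uncertain because 83.9% of its 31-base words occur in other genes. The Y-linked genes with the lowest p, Gm28827, Gm28337, Gm28510 and Gm20777, had log2 fold changes of 3.68, 5.52, 2.41 and 1.97 and belong to multicopy families (74.2% to 100% of words shared), so none of these values can be assigned to a single copy, and Gm28510 was at 1.27 with length and GC trends removed. Of the 5 Y-linked genes with under 5% of words shared, Uty, Ddx3y, Tspy-ps and Eif2s3y rose, and Usp9y was at 0.55 (edgeR adjusted p = 0.134). Cdk16, Gm2098 and these 5 genes were chosen after their values were seen, as were the other list members named to account for a count of 5 or fewer. In the fixed list of sex-linked genes transcribed after meiosis, 24 of 33 rose and 1 fell (24 and 1 adjusted over the list alone), with a median of 1.52 and a camera adjusted p of 3.93e-15. With an estimated correlation the call was lost (adjusted p = 0.107), and the median was 1.1 with length and GC trends removed. Cypt15 and Cypt1 of this list had log2 fold changes of 2.47 and 2.07, and the gene that fell, Mageb3, lies on chromosome 2. Akap4, an abundant X-linked gene of the fibrous sheath of the flagellum, was at 756 CPM in wild type and 732 CPM in SKO (edgeR adjusted p = 0.892).

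Of 42 acrosome genes 21 rose and 3, Adam1b, Actl9 and Zp3r, fell (22 and 3 adjusted over the list alone). The median was 0.38 and the camera adjusted p 0.000507, but 0.289 with an estimated correlation. Spaca5, Cylc1 and Actrt1, all X-linked, had log2 fold changes of 2.25, 1.75 and 1.89, and the autosomal lysozyme-like gene Lyzl1 had 1.21. Cylc1 was at 1.10 and Lyzl1 at 0.75 with length and GC trends removed. Early round spermatid genes, 14 of 20 of which also stand in another list, rose in 12 cases with no fall (13 and 0 adjusted over the list alone), with a median of 0.44 and a camera adjusted p of 0.000207 (adjusted p = 0.324 with an estimated correlation). Ssxb1, Spaca9 and Lyzl6 of this list had log2 fold changes of 1.74, 1.03 and 0.91. Ssxb1 is X-linked and uncertain, with 67.1% of its words shared, and was at 1.12 with length and GC trends removed. Elongating spermatid genes rose in 11 of 25 cases with no fall (11 and 0 adjusted over the list alone), among them Ropn1 at 0.88, Tex33 at 0.74 and the sperm glycolytic enzyme gene Gapdhs at 1.37 (0.89 without SKO replicate 3). The median was 0.30 and the camera adjusted p 0.0294, or adjusted p = 0.324 with an estimated correlation, and the call was also lost without wild type replicate 2 (camera adjusted p = 0.0634). Without SKO replicate 3 the median was 0.18. Oaz3 of the same list was at 0.64, an uncertain value because 55.8% of its exonic bases lie in exons of Mrpl9 and Tdrkh on the opposite strand, and at 0.40 with total-count scaling.

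Genes for chromatin packaging in condensing spermatids rose in 5 of 12 cases with no fall (5 and 0 adjusted over the list alone), with a median of 0.42. The camera adjusted p was 0.038 and was 0.659 with an estimated correlation. It was 0.14, with a median of 0.22, without SKO replicate 3 and 0.077 without wild type replicate 2, and the list summed to 5320 CPM in SKO replicate 3 against 3690 and 4050 CPM in the other SKO libraries. Protamine gene Prm1 rose from 376 ± 29 to 621 ± 140 CPM (SD, n = 3), a log2 fold change of 0.73. Beside it were Hils1 at 0.72, Prm3 at 0.77, the transition protein gene Tnp2 at 0.62 and the X-linked H2al1n at 1.60, of whose words 44.4% are shared. Prm1 was at 0.43 and Prm3 at 0.49 with length and GC trends removed. Prm3 was at 0.44 without SKO replicate 3, and its rise did not pass with total-count scaling (edgeR adjusted p = 0.072) or without wild type replicate 2 (adjusted p = 0.058). Prm2 and Tnp1 had log2 fold changes of 0.42 and 0.17 (edgeR adjusted p = 0.0804 and 0.56). In the list of testis and replacement histone variants 4 of 13 rose and 2 fell (4 and 2 adjusted over the list alone), with a median of 0.37 (0.22 without SKO replicate 3) and a camera adjusted p of 0.391. H3f3a and H3f3b, which encode histone H3.3, and the linker histone genes H1f0 and H1f6 rose, by 0.78, 1.18, 1.68 and 0.86 on the log2 scale, and the macroH2A genes Macroh2a1 (-0.96) and Macroh2a2 (-1.38) fell. H3f3a is less certain, with 31.55% of its words shared and 22.8% of its exonic bases in exons on the opposite strand. Of 19 regulators of histone exchange 7 rose and 4 fell (8 and 4 adjusted over the list alone), with a median of 0.30 and a camera adjusted p of 0.491. Ing2 and the proteasome activator gene Psme4 had log2 fold changes of 0.85 and 0.81, and the acetyltransferase gene Kat5 (-0.99), Cdyl (-0.71), Nutm1 (-0.81) and Camk4 (-0.61) fell. Removing length and GC trends left Kat5 at -0.63, Cdyl at -0.39 and Macroh2a1 at -0.62.

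Heterochromatin and chromocenter genes moved in both directions, with 5 of 29 higher and 5 lower over all genes and adjusted over the list alone. Hmga1, whose product binds AT-rich DNA, had a log2 fold change of -2.56, an uncertain value since 73.3% of its words are shared. Lmnb2 (-1.05), Daxx (-1), Cbx5, which encodes the heterochromatin protein HP1 alpha (-0.62), and the H3K9 methyltransferase gene Suv39h2 (-0.48) also fell. Morc2a (1.57), Hmgb2 (1.53), the X-linked Scml2 (1.07), Hells (1.04) and Mphosph8 (0.91) rose. The median of 0.05 and the mean of 0.01 were positive while camera's direction was negative (adjusted p = 0.993). Among 27 spermatid transcription regulators 5 rose and 4 fell (4 and 3 adjusted over the list alone), with a median of 0.19 (0.089 without SKO replicate 3) and a camera adjusted p of 0.674. Taf7l (1.14, X-linked), Mybl1 (0.98) and Fhl5 (0.79) rose, beside Tbpl1 (0.58) and Crem (0.38), an activator of postmeiotic genes. Mybl1 was at 0.62 and Fhl5 at 0.43 after removal of length and GC trends. Zmynd15 fell from 88.1 ± 22.4 to 22.1 ± 6.49 CPM (SD, n = 3), and Kctd19 (-1.08), Rfx4 (-0.78) and Rfx3 (-0.50) also fell.

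Flagellum genes rose in 13 of 54 cases and fell in 11 (13 and 11 adjusted over the list alone), with a median of -0.04 and a camera adjusted p of 0.993. Fsip2 was at 0.91 (0.58 with length and GC trends removed) and Tekt5 at -0.83. Manchette and head shaping genes rose in 7 of 37 cases and fell in 8 (7 and 10 adjusted over the list alone), with a median of -0.01 (-0.18 to -0.01 when each library was left out, lowest without SKO replicate 1) and a camera adjusted p of 0.908. The kinesin gene Kif3b (1.34), Meig1 (1.29) and the intraflagellar transport gene Ift20 (1.19) rose. Germ granule and stored mRNA genes rose in 11 of 41 cases and fell in 6 (11 and 6 adjusted over the list alone), with a median of 0.19 (0.07 without SKO replicate 3) and a camera adjusted p of 0.515. Dazl, an RNA-binding regulator of germ cell translation, rose from 20.8 ± 1.24 to 72.2 ± 11.2 CPM (SD, n = 3). Pabpc1 and Paip2 had log2 fold changes of 0.80 and 0.79, and Tdrd7 had -0.92.

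Cytosolic ribosomal protein genes rose in 62 of 79 cases and fell in 1, Rpl13a (64 and 1 adjusted over the list alone). The median was 0.86 (quartiles 0.62 and 1.11) and the camera adjusted p 5.77e-11, but 0.659 with an estimated correlation. Their summed level was 5710 ± 325 CPM in wild type and 10300 ± 2290 CPM in SKO (SD, n = 3), with 12900 CPM in SKO replicate 3 against 8640 and 9330 CPM in the other SKO libraries. The testis-specific Rpl39l had a log2 fold change of 1.28 (0.75 with length and GC trends removed), beside 1.94 for Rps15 and 1.20 for Rpl23, which share 50.7% and 41.7% of their words with other genes. Nuclear-encoded genes of oxidative phosphorylation rose in 54 of 73 cases and fell in 4, among them Ndufs1, Atp5a1 and Sdhd (56 and 5 adjusted over the list alone). The median was 0.83 and the camera adjusted p 5.77e-11, or adjusted p = 0.542 with an estimated correlation. Examples are Ndufv2 of complex I, from 699 ± 61.3 to 1540 ± 148 CPM (SD, n = 3), and Atp5o at 1.17, of whose words 39.8% are shared. Ndufa1 at 1.86 and Cox7b at 3.51, the latter from 1.04 CPM in wild type, are among the 3 X-linked members of this list. The sums of this list were 15100, 16400 and 19600 CPM in SKO replicates 1, 2 and 3. Sertoli markers were also higher in the SKO libraries, with a median log2 fold change of 3.34, but among these libraries their sums ran the other way, at 236, 136 and 74.2 CPM. The sums of blood, endothelial and macrophage markers were 49.9, 44.7 and 67 CPM, highest in SKO replicate 3. Those of Leydig and peritubular markers were 127, 103 and 109 CPM. Translation factors rose in 19 of 59 cases and fell in 8 (19 and 8 adjusted over the list alone), with a median of 0.25 (0.135 without SKO replicate 3) and a camera adjusted p of 0.211. The X-linked release factor gene Gspt2 (1.73), Mcts2 (1.02, or 0.66 with length and GC trends removed), Eif1 (0.95) and Eif3g (0.85) had the lowest p. Eif4g1 (-1.05) and Eif3b (-1.04) were among those that fell. Of 18 genes of the hypusine and polyamine pathway 4 rose and 1, Paox, fell (4 and 1 adjusted over the list alone), with a median of 0.26 and a camera adjusted p of 0.232. Paox was at 1.81 CPM in wild type and 0.321 CPM in SKO and shares 33.1% of its words with other genes. Srm, which encodes spermidine synthase, was at 0.94, Azin1 at 0.55, Sat2 at 1.93 (from 0.282 to 1.08 CPM, near the floor) and Oaz3 at 0.64. The rise of Azin1 did not pass with total-count scaling (edgeR adjusted p = 0.139) or without wild type replicate 1 or 3 (adjusted p = 0.0791 and 0.0668). Azin1 was at 0.39 with length and GC trends removed and did not pass (edgeR adjusted p = 0.0782).

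Genes of the integrated stress and unfolded protein responses rose in 4 of 38 cases and fell in 9 (4 and 9 adjusted over the list alone), with a median of -0.09 (-0.019 without wild type replicate 2) and a camera adjusted p of 0.586. Chac1 (-3.79) and Edem1 (-2.11) fell, and the endoplasmic reticulum genes Manf (0.98), Canx (1.14), Dnajb9 (0.89) and Hsp90b1 (0.39) rose. Among 29 heat shock chaperone genes 6 rose and 3 fell (5 and 3 adjusted over the list alone), with a camera adjusted p of 0.993. Bag3 fell from 38 ± 1.56 to 4.51 ± 1.16 CPM (SD, n = 3), Hsph1 and Hspa8 had log2 fold changes of -1.04 and -0.69, and Hspb9 and Hsf2 had 0.95 and 0.75. With length and GC trends removed Hsf2 was at 0.30 and did not pass (edgeR adjusted p = 0.108). The median of that list was 0.07 and camera's direction positive, while its mean was -0.01. Genes of the p53 response and cell death rose in 4 of 21 cases and fell in 3 (4 and 3 adjusted over the list alone), with a median of 0.19 (0.11 to 0.21 when each library was left out, lowest without wild type replicate 1) and a camera adjusted p of 0.561. Btg2 (2.53), Fas (2.63), Ccng1 (1.42) and Cycs (1.02) rose, and Tnfrsf10b (-1.49), Zmat3 (-0.59) and Trp53 (-0.84) fell. In wild type Btg2 was at 0.852 CPM and Ccng1 at 1.37 CPM, so their fold changes start near the floor. Cycs shares 32% of its words with other genes. Of 12 interferon response genes 1, Ifi27 (0.84), rose and 2, Mx1 (-1.54) and Cmpk2 (-1.36), fell (1 and 2 adjusted over the list alone). Their median of 0.09 was positive while the mean of -0.06 and camera's direction were negative (adjusted p = 0.84). Proteasome genes rose in 11 of 35 cases and fell in 3 (11 and 3 adjusted over the list alone), with a median of 0.19 and a camera adjusted p of 0.211. Psma6, Psmb3, Psma7 and Psmb2 had log2 fold changes of 1.18, 1.23, 1.19 and 0.89, and Psmd2 (-0.93), Psmd3 (-0.98) and Psmb5 (-0.85) fell. Autophagy and lysosome genes rose in 8 of 27 cases and fell in 9 (8 and 9 adjusted over the list alone). Among them Gabarapl1 (1.04) and the X-linked Lamp2 (1.48) rose, and Sqstm1 (-1.22) and Atg13 (-1.10, or -0.72 with length and GC trends removed) fell. The median of -0.04 and camera's direction were negative while the mean of 0.08 was positive (adjusted p = 0.908), and the median was -0.15 without SKO replicate 1.

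**Figure D2:**
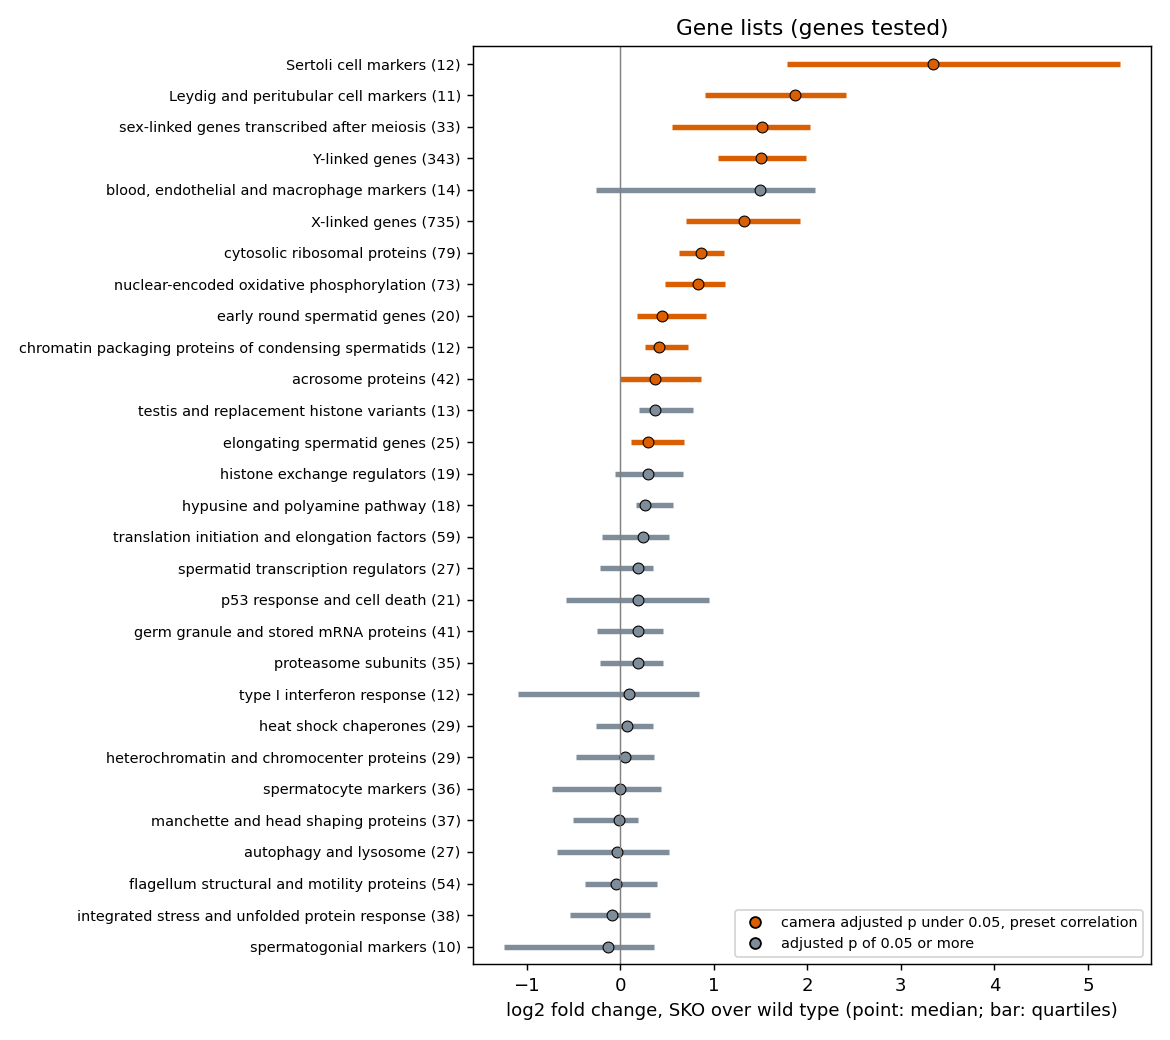
Median (point) and quartiles (bar) of log2 fold changes, SKO over wild type (horizontal axis), of each gene list, with the number of genes tested in brackets. Orange lists had a camera adjusted p under 0.05 with a preset correlation; the medians ran from -0.14 for spermatogonial markers to 3.34 for Sertoli cell markers.

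Markers of other cell types that the sort could hold differed in direction. Of 21 Sertoli markers fixed in advance 12 were in the table, so the values below leave the absent ones out. Sertoli markers rose in 9 of 12 cases with no fall (10 and 0 adjusted over the list alone), with a median of 3.34 and a camera adjusted p of 1.09e-06, or adjusted p = 0.324 with an estimated correlation. The summed level was 236, 136 and 74.2 CPM in SKO replicates 1, 2 and 3 and 4.41, 7.6 and 14.8 CPM in wild type replicates 1, 2 and 3. Cst9 (28.4 ± 11.2 CPM in SKO), Defb19 (18.5 ± 6.06), Cst12 (14.4 ± 4.01) and Aard (9.18 ± 6.07) had the lowest p, and Clu was at 3.54 ± 3.6 CPM in wild type and 45.7 ± 39.2 CPM in SKO (SD, n = 3; edgeR adjusted p = 0.0661). Leydig and peritubular markers rose in 4 of 11 cases, Igf1 (2.38), Acta2 (1.87), Star (1.92, from 0.609 to 2.32 CPM) and Insl3 (5.90), with no fall (4 and 0 adjusted over the list alone). Exons of Jak3 overlap 64.8% of the exonic bases of Insl3, so its value is uncertain. Insl3 had 0 CPM in wild type replicates 1 and 2 and 0.256 CPM in wild type replicate 3. Its log2 fold change ran from 5.34 to 11.18 over the alternatives, and the rise did not pass in limma-voom (7.12, adjusted p = 0.0702) or without SKO replicate 3 (edgeR adjusted p = 0.0655). The median was 1.87 and the camera adjusted p 0.0173, but 0.542 with an estimated correlation and 0.0925, with a median of 1.75, without SKO replicate 3. Without wild type replicate 3 the median was 3.89. Blood, endothelial and macrophage markers rose in 4 of 14 cases and fell in 3 (5 and 3 adjusted over the list alone), with a median of 1.49 and a camera adjusted p of 0.689. Tyrobp (4.53), H2-Eb1 (2.61), Lyz2 (2.06) and Hba-a2 (1.73) rose, and Kdr (-2.06), Adgre1 (-2.77) and H2-Ab1 (-0.75) fell. Lyz2 shares 32.8% of its words with other genes, and the fall of H2-Ab1 did not pass without wild type replicate 1 or 3 (edgeR adjusted p = 0.0506 and 0.0556) or with length and GC trends removed (-0.43, adjusted p = 0.143). Spermatogonial markers rose in 1 of 10 cases, the X-linked Rhox13 (1.13), and fell in 3, Kit (-2.46), Dmrt1 (-1.82) and Sohlh2 (-1.13) (1 and 3 adjusted over the list alone). The median was -0.14 and the camera adjusted p 0.562. The rise of Rhox13 did not pass with total-count scaling (edgeR adjusted p = 0.0637) or without SKO replicate 3, wild type replicate 2 or wild type replicate 3 (adjusted p = 0.078 to 0.0819). The fall of Sohlh2 did not pass without SKO replicate 2, wild type replicate 1 or wild type replicate 2 (edgeR adjusted p = 0.0553 to 0.0816). Spermatocyte markers rose in 8 of 36 cases and fell in 10 (9 and 11 adjusted over the list alone), with a median of -0.0030 and a camera adjusted p of 0.518. Sycp3 of the synaptonemal complex (1.82) and Pttg1 (0.95) rose, and the kinase genes Aurkc (-2.25) and Plk1 (-1.10) fell. Sycp3 is uncertain, since 52.2% of its exonic bases lie in exons of Chpt1 on the opposite strand and its log2 fold change was 0.72 with length and GC trends removed, and so is Aurkc, with 76% of its words shared.

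**Figure D3:**
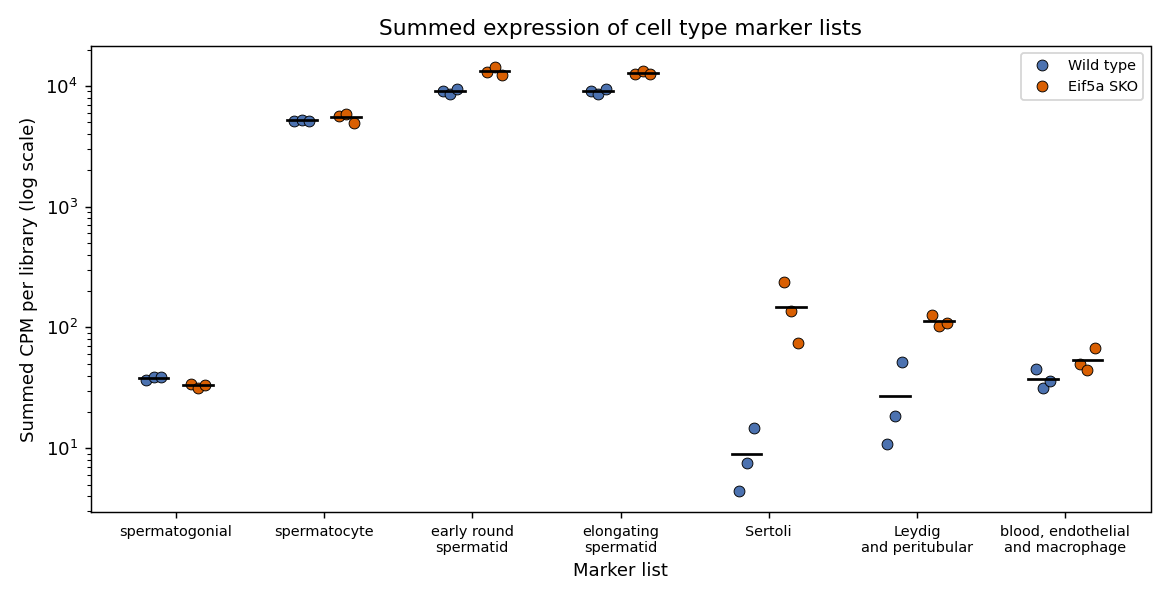
Summed CPM of the marker lists of 7 cell types (vertical axis, log scale) in each library, wild type in blue and SKO in orange, with a line at the mean of each group. Sertoli markers summed to 74.2 to 236 CPM in the SKO libraries and 4.41 to 14.8 CPM in wild type, while early round spermatid genes summed to 13200 ± 1010 and 9000 ± 415 CPM (SD, n = 3).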

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

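The fits with length and GC trends removed and without X-linked and Y-linked genes were chosen after the data were seen, as were all alternatives for the X-linked comparison except the filter, the block and the left-out libraries. Eif5a stayed past the threshold in every alternative, with -6.85 to -6.68 when each library was left out, -6.75 with the replicate number as a block and -6.51 with length and GC trends removed. Leaving out each library gave 3058 to 4321 genes higher, 3029 to 4823 lower, 9 to 11 lists called and an X-linked minus autosomal difference of 1.31 to 1.38. The filter of at least 5 CPM in 3 libraries tested 10279 genes, fewer than before by construction, and called 2755 lower, 1221 higher by 2-fold or more and 1256 lower by 2-fold or more. With an estimated correlation 1 list was called. The block gave 3558 genes higher and 3735 lower and shared 85.4% of the calls. Deviations from the group means correlated by -0.0655 to -0.0221 across genes between libraries with the same number. These values show no sign of a pairing by number but cannot exclude one. Leaving out mitochondrially encoded genes was not run, as the table holds 0 of them, and the fit without X-linked genes gives no X-linked value.

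Over 129 named genes and 2282 comparisons with an alternative, 2253 kept direction and side of the threshold, 26 lost their call, 3 gained it and 0 reversed in sign. Over 29 lists and 520 comparisons, 474 kept both, 10 lost the call, 3 gained it and 33 changed the sign of the median, 1 of them of a list that was called. That list, the sex-linked genes, holds 2 autosomal members, whose median was -0.18 when X-linked and Y-linked genes were left out. The 520 comparisons leave out the other list tests. Camera called 11 lists with a preset correlation but 1 with an estimated correlation, and fry called 16.

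Medians with the other sign were as follows, and the cause was not tested beyond the shift of all genes with total counts. With total counts they were -0.195 for heterochromatin, -0.0495 for transcription regulators, -0.0529 for germ granules, -0.16 for heat shock, -0.0526 for p53, -0.157 for interferon and -0.0485 for proteasome genes. With upper-quartile factors manchette genes were at 0.021 and spermatocyte markers at 0.03. With no filter spermatogonial markers were at 0.0476. With at least 5 CPM manchette genes were at 0.015, interferon genes at -0.23 and spermatogonial markers at 0.0653. With quality weights in limma-voom manchette genes were at 0.00342, stress response genes at 0.000416 and spermatocyte markers at 0.0839, and with the 20 most abundant genes left out of library sizes spermatocyte markers were at 0.000275. With length and GC trends removed flagellum genes were at 0.0698, stress response genes at 0.0782 and autophagy genes at 0.0698. Without X-linked and Y-linked genes flagellum genes were at 0.0177, manchette genes at 0.0465 and spermatocyte markers at 0.0286. Leaving out each library gave -0.148 to 0.131 for heterochromatin, -0.137 to 0.011 for flagellum, -0.295 to 0.587 for interferon, -0.251 to 0.0468 for spermatogonial and -0.267 to 0.0257 for spermatocyte genes.

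Camera's call of chromatin packaging genes was lost with total counts (adjusted p = 0.115), with at least 5 CPM (0.116) and with length and GC trends removed (0.153), and elongating spermatid genes lost it with total counts (0.115) and at least 5 CPM (0.0892). Leydig and peritubular markers lost it with at least 5 CPM (adjusted p = 0.0786). With length and GC trends removed, histone exchange regulators (adjusted p = 0.0329), hypusine and polyamine genes (0.0465) and translation factors (0.0118) were called with a preset correlation. With an estimated correlation, run only without that removal, their adjusted p was 0.659, 0.569 and 0.365. With 67 genes changed 1.5-fold in simulated counts 10.4% were called. Few genes were changed there, whereas 42.2% of tested genes were called in the real comparison, where the adjustment is milder. The simulated share therefore does not tell how many small changes were missed here. Depth was not varied apart from replicate spread.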

Other observations

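The gene families and chromosome 14 blocks below were picked after the fold changes were seen, and the tests by splits of the libraries, by sex-linked spermatid genes and by spermatogonial markers were chosen only after the result was seen. Genes of the rodent-specific Speer family rose in 11 of 13 cases and fell in 1, with a median log2 fold change of 0.80. On chromosome 14, 83 of 133 genes that start before 10 Mb were higher and 9 lower (median 1.06), and 80 of 104 genes that start from 40 to 45 Mb were higher and 0 lower (median 1.61) in edgeR's test, while the other 719 genes of the chromosome had a median of 0.01, whose sign did not hold with total counts (-0.23), RLE factors (-4.76e-05) or length and GC trends removed (-0.07). With these trends removed the medians were 0.621 and 1.23 for the blocks and 0.714 for Speer genes. Genes of these blocks share a median of 92.8% and 86.3% of their 31-base words with other genes, so single copies cannot be told apart. All 7 X-linked Btbd35f genes tested rose, with a median of 2.39 (1.85 with the trends removed) and 95.1% of words shared. None of these families was called with an estimated correlation (camera adjusted p = 0.197 for Speer, 0.25 and 0.197 for the blocks and 0.25 for Btbd35f).

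Mitochondrial ribosomal protein genes rose in 45 of 77 cases and fell in 4, with a median of 0.57. Cadherin genes, which encode cell adhesion proteins, fell in 8 of 13 cases with 0 rises (median -1.04), Galnt genes, which start O-linked glycan chains, fell in 7 of 13 cases with 1 rise (median -0.67), and tubulin genes fell in 6 of 14 cases with 2 rises (median -0.42). These signs held with RLE, total-count and upper-quartile scaling, and with length and GC trends removed the medians were 0.601, -0.79, -0.64 and -0.37. With an estimated correlation the camera adjusted p was 0.251, 0.197, 0.25 and 0.44 for these 4 families.

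The 6 libraries can be parted into 3 and 3 in 10 ways, too few for a share under 0.05. Every split but the real one holds both genotypes in each group in unequal numbers. Such a split keeps part of the genotype difference and puts the rest into the spread within groups, which lowers gene calls. It therefore does not show what would be called without a genotype effect. The real split gave 8339 genes higher or lower and 4865 of 2-fold or more, and the highest of the other splits gave 0 and 0 in edgeR, with 1 split of 10 as large for each. At an unadjusted p under 0.05 the real split gave 9948 genes and the other splits at most 444, and limma-voom called 0 in the others. Camera with a preset correlation called 11 lists in the real split and 15 in the split of SKO replicate 1 with wild type replicates 1 and 2 against the rest, so 2 of 10 splits gave as many, and each of the 9 other splits called at least 6. The X-linked minus autosomal difference was 1.36 in the real split and at most 0.476 in size in the others, with 1 of 10 as large.

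X-linked genes lay above autosomal genes by 1.36 on the log2 scale in SKO. Removing each library's trend with exonic length and GC left a difference of 1.04, and X-linked genes with under 5% of words shared kept 1.16, both of which argue against these trends or shared reads as the whole cause. The list of sex-linked genes transcribed after meiosis had a median of 1.52, above that of all X-linked genes (1.32). Of its 33 members 21 are X-linked and 10 Y-linked, so its rise largely restates the pattern. It was also not limited to genes that somatic cells lack. It therefore cannot decide whether RNA of somatic cells contributes. A different mix of spermatid steps and an effect of the genotype on transcription of the sex chromosomes were not tested and stay open.

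Sertoli markers had a median log2 fold change of 3.34 in SKO, and the sort for round spermatids would remove Sertoli cells. A second list of 17 Sertoli genes, written before its values were seen, had a median of 1.52 over 11 tested, with 5 higher and 2, Espn and Cdh2, lower in edgeR's test, which is consistent with RNA of Sertoli cells in the SKO libraries. The most abundant markers there were Clu at 45.7, Cst9 at 28.4, Ctsl at 19.5 and Defb19 at 18.5 CPM. Spermatogonial markers did not rise with Sertoli markers. They summed to 38 CPM in wild type and 33.1 CPM in SKO. Their median log2 fold change of -0.14 (SD 1.18) lay 3.48 below that of Sertoli markers (permutation test over 12 and 10 genes, two-sided, p = 0.00106). Both medians were known before this test was chosen, so its p adds no support. Medians were 1.87 for Leydig and peritubular and 1.49 for blood, endothelial and macrophage markers. In wild type 8 of 10 spermatogonial but 2 of 12 Sertoli markers reached 1 CPM, so signal already present could hide a small rise. A lower share of round spermatids that raised other cell types is therefore not decided. The permutation test treats genes as independent, whereas Sertoli markers varied together (estimated correlation 0.353). Its p thus measures spread among genes and not among libraries. Expression of the Sertoli markers in SKO spermatids themselves was not tested and stays open.

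Ribosomal protein and respiratory chain mRNAs had medians of 0.86 and 0.83 in SKO. With length and GC trends removed the medians were 0.847 and 0.678, which argues against these trends as the whole cause. RNA of somatic cells cannot be told apart from a rise in spermatids. The SKO library with the highest Sertoli sum (236 CPM) had the lowest ribosomal and respiratory chain sums (8640 and 15100 CPM). The SKO library with the lowest Sertoli sum (74.2 CPM) had the highest (12900 and 19600 CPM). Blood, endothelial and macrophage markers, however, summed to 49.9, 44.7 and 67 CPM in SKO replicates 1, 2 and 3, highest in that same library. Leydig and peritubular markers summed to 127, 103 and 109 CPM. The order of so few libraries cannot decide the question. The testis-specific members Cox6b2, Cox7b2, Cox8c, Rpl10l and Rpl39l had a median of 0.661, above 0.431, which is 0.5 of the other members' median, by less than their SD of 0.483. A change in spermatid translation or in the mix of spermatid steps stays open and was not tested.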
